A study of Danio rerio with 9 samples.

How the data were processed

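The series describes RNA sequencing of 9 cultures of zebrafish brain progenitor cells, in 3 age groups of 3 cultures. What was analysed here is the authors' 3 merged transcript files, each a list of exons titled for 2 of the words old, mid and young, of which mid is not a label of any sample. Per the submitters' processing notes, the tools used on the reads included TopHat2 2.1.1, a spliced-read aligner, Cufflinks 2.2.1, a transcript assembler, and Cuffdiff, which compares expression between groups. The roles, order and settings of these tools, the genome build and the annotation release are not given in the sources used here. Coordinates are therefore printed as the deposited files give them, with 1-based starts and ends and no build name. Gene names are those the deposited files pair with each transcript, and reference transcripts carry Ensembl zebrafish transcript names.

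Each line of the deposited files is an exon with a chromosome, a start, an end, a strand and a set of names. The score field was empty in every line, and no field held a read count, a coverage or an expression value. No column named a sample, so the files were treated as pooled over all samples. Sequencing depth is unknown for every sample, and no confidence interval for a level of expression can be given. Tests planned for expression values (old against young, old against very young and young against very young) were not run, because no value per sample was analysed here.

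Exon lines were grouped into transcripts by transcript identifier. The 3 files were compared transcript by transcript on chromosome, strand and exon coordinates, then on every other field. Transcripts were counted by class code, the code with which Cufflinks relates a transcript to the reference. An equals sign marks the same intron chain as a reference transcript, and j marks an isoform that shares at least 1 junction with a reference transcript but has another intron chain. Reference transcripts were recognised by their Ensembl name, and assembler transcripts by the prefix that Cufflinks gives. Each intron, start and end of a class j isoform was looked up among those of the reference transcripts on the same strand. An intron chain was also split into the fewest runs of consecutive introns that each occur in 1 reference transcript of the locus. This measure was written after the introns had been seen, and it replaced a first one, cover by whole reference chains, that most isoforms did not meet.

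In all, 12 gene lists for brain cell types, proliferation, senescence, inflammation and related processes, with 276 genes, and the rule for named genes were fixed before the files were opened. The rule takes the 10 gene names with the most class j isoforms and up to 4 members of each list with the most. Its further parts, unannotated loci and genes that differ between the files, had no members. The design took class j isoforms as assembled from the reads, which their almost wholly annotated introns leave open, and the planned test was kept as written. For each list, the genes with at least 1 class j isoform were compared with all other gene names by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 12 lists and a threshold of 0.05. Odds ratios carry a 95% interval from the variance of the log odds ratio. This test runs over genes, which are not replicates. As alternatives, genes were assigned by their nearest reference transcript, transcripts were counted in place of genes, single-exon transcripts were left out, and 10000 random lists matched on the number of annotated exons replaced the background. After the introns had been examined, random lists matched on the number of annotated transcripts and a background of genes with at least 2 annotated transcripts were added. Matching used exact values up to 6 and wider classes above. The report gives the random lists matched on annotated transcripts beside the main test.

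The measures were tested on simulated data. All 400 simulated isoforms were recovered as the kind they had been made as, and all 59 transcripts with a shifted exon were found with 0 false calls. In 200 simulations over the 29035 gene names in which class j isoforms depended on the number of annotated transcripts alone, Fisher's exact test called at least 1 list in 57.0% of the runs. It called the cell cycle list in 35.0% of them, while matching on annotated transcripts called it in 0.5%. With the odds of the cell cycle list raised 6-fold, Fisher's exact test called it in 99.5% of the runs and the matched test in 36.0%. The analysis used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.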

Results

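The study cultured progenitor cells from the brains of zebrafish of the AB wild-type strain at 3 ages. Brains were dissociated with a neural tissue kit, and the cells were grown in flasks with EGF and FGF, growth factors that keep neural stem cells dividing. The 9 cultures fall into 3 groups of 3, labelled very young, young and old. The very young cultures came from fish of 3 months, with 10 brains pooled for each. In the young group, 2 cultures came from fish of 5.5 months and 1 from fish of 8.5 months, with 5 brains pooled for each. In the old group, 2 cultures came from fish of 30 to 31 months and 1 from fish of 26 to 28 months, again with 5 brains each. The labels differ among themselves: the series design names ages of 3, 8 and 30 months, and the extraction protocol states 10 brains per culture. Old replicate 1 and young replicate 1 are titled CellBind, a flask brand, and the other cultures MACS, the maker's name of the dissociation kit. The CellBind cultures are those of 26 to 28 and of 8.5 months, so title and age cannot be told apart within these groups. Pool size separates the very young group from both others.

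The design asks how the transcriptome of these cells differs between ages. The 3 merged transcript files, each titled for 2 of the words old, mid and young, describe the same 68373 transcripts at 31073 loci under 29035 gene names. Every transcript had the same chromosome, strand, exons, class code and gene name in all 3 files, so the files hold no difference between the ages and cannot show whether there was one. Between pairs of files, 5562 to 5945 of the 10596 assembler-given transcript names differed, each time with the same isoform number. Protein identifiers differed for 6392 to 8711 transcripts, but they grouped the same transcripts. Progenitor genes such as gfap, proliferation genes such as pcna and senescence genes such as cdkn1a therefore have no value by age in what follows, and none of the 3 age comparisons could be tested.

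The catalogue itself covered 25 chromosomes and, with unplaced scaffolds and the mitochondrial genome, 366 sequences. Of its transcripts, 57777 carried Ensembl names and 10596 carried assembler names. Among the assembler-named transcripts, 2249 matched the intron chain of a reference transcript and 8347 were class j isoforms, which share a junction with a reference transcript but have another intron chain. No transcript had any other class code, so no unannotated intergenic, antisense or intronic transcript was added to the reference. Class j isoforms made up 12.2% of the transcripts and fell in 5934 gene names, 20.4% of all.

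Class j isoforms were built almost entirely of annotated parts. Of their 110465 introns, 110429 were annotated on the same strand. The remaining 36 introns, 1 in each of 36 isoforms of 28 genes, joined splice sites that were both annotated. Both ends of 8240 isoforms (98.7%) lay on annotated exon boundaries. The intron chain of 6169 isoforms (73.9%) was made of 2 runs, each found in 1 annotated transcript, and that of 761 (9.12%) was an unbroken part of a single annotated chain. At the 17223 loci with 1 annotated transcript there were 0 class j isoforms, whereas 5910 of the 13850 loci with more than 1 carried them (42.7%). The share was 24.8% at loci with 2 annotated transcripts, 52.5% at loci with 3 and 80.9% at loci with 5. These are complete counts of the catalogue and carry no sampling error.

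**Figure D1:**
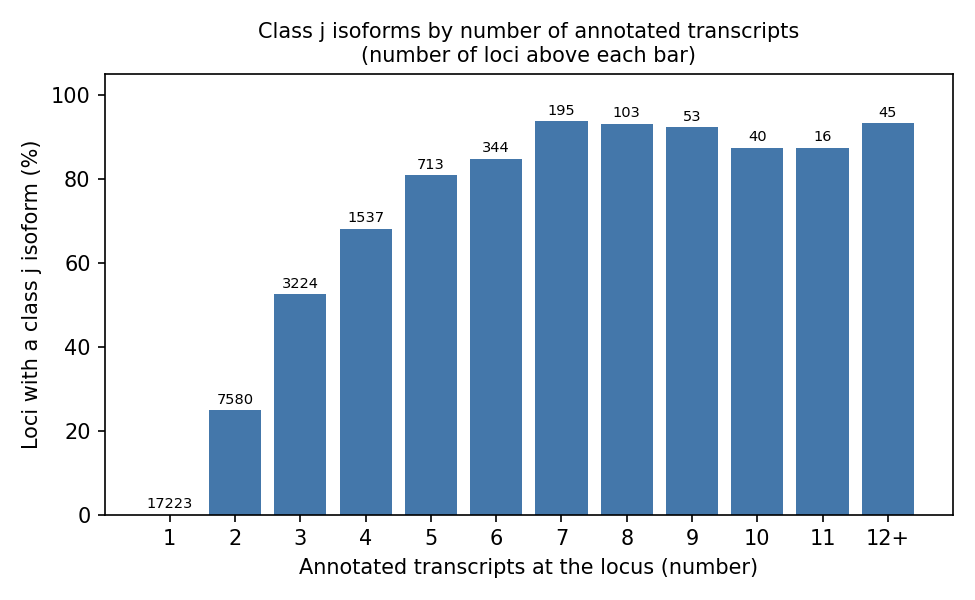
Percentage of loci with at least 1 class j isoform (y axis) by the number of annotated transcripts at the locus (x axis, the last bar holding 12 or more), with the number of loci above each bar. The share is 0 at the 17223 loci with 1 annotated transcript and 24.8% at those with 2, and it is above 80% from 5 annotated transcripts on.

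The gene with the most class j isoforms was cast, which encodes the calpain inhibitor calpastatin, with 23 isoforms beside 18 annotated transcripts (chromosome 21, 11473260 to 11564415, minus strand). The muscle gene ldb3a had 13 beside 20 annotated transcripts (chromosome 13, 22346315 to 22422237). The RNA-binding protein gene msi2b, a member of the Musashi family known from neural stem cells, had 11 beside 15 (chromosome 15, 30543904 to 30952156). The uncharacterised genes si:ch211-222m2.1, zgc:113886 and si:ch211-225b10.1 had 11, 10 and 9, and lrrfip1a had 9. The immunoglobulin heavy chain segment ighv1-4 also had 9, at a locus that holds 6 other segments. Counts for si:dkey-16p6.1 (13 isoforms) and ccbl2 (10 isoforms) are uncertain, because these names are spread over 18 and 2 loci.

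The gene lists were compared to ask whether genes of particular brain cell types or processes carried class j isoforms more often than other genes. Of the 276 listed genes, 263 were found by symbol, and 77 of them (29.3%) had at least 1 class j isoform. The cell cycle list had the highest share, with 13 of 26 genes against 20.4% of all other genes. Among its members, rrm2, a subunit of ribonucleotide reductase, had 3 isoforms, and ccnb1 (cyclin B1), foxm1 and mcm6 had 2 each. The odds ratio was 3.90 (95% interval 1.81 to 8.42, Fisher's exact test, two-sided, adjusted p = 0.00895). Random lists with the same numbers of annotated transcripts held 10.7 such genes on average, and 95% of them held 7 to 14, a range that includes the 13 observed (odds ratio 1.43, adjusted p = 0.67, permutation test). The rrm2 name covers 2 loci. The mcm6 locus also holds si:ch73-71c20.5, and the 2 isoforms of mcm6 contain introns annotated to each of these genes.

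No other list passed the threshold in Fisher's exact test over all genes. The list of DNA methylation genes, histone modifiers and sirtuins came nearest, with 10 of 23 genes (43.5%, odds ratio 3.00, interval 1.31 to 6.84, unadjusted p = 0.0156 and adjusted p = 0.0936 by Fisher's exact test). Its members included the DNA methyltransferase dnmt3ba with 3 isoforms, the histone deacetylase hdac3 and the methylcytosine dioxygenase tet3 with 2 each, and the chromatin remodeller chd7 with 1. Matched random lists held 8.49 such genes on average and 5 to 12 in 95% of cases (odds ratio 1.32, adjusted p = 1, permutation test). In the EGF and FGF list, 9 of 25 genes had class j isoforms (36.0%), among them fgfr2 with 3, etv5a with 2, and fgfr1a and egfra with 1 each (odds ratio 2.19 to other genes and 1.08 to matched lists). In the senescence and telomere list the number was 8 of 23 (34.8%), with 5 isoforms of mdm2, 2 of lmnb1 and 1 of the telomerase gene tert (odds ratio 2.08 to other genes and 1.01 to matched lists). The inflammatory list had 6 of 19 (31.6%), with 1 isoform each of stat1b, mxa, stat3 and mmp9 (odds ratios 1.80 and 1.13).

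Among the cell type lists, that of radial glia and neural stem cells had 8 of 31 genes with class j isoforms (25.8%). Besides msi2b, these included the transcription factor genes pax6a with 5 isoforms and pax6b with 3, and msi1 with 2. Neuronal genes numbered 6 of 24 (25.0%), with 4 isoforms of the adhesion molecule gene ncam1a, 3 of map2 and 2 each of the glutamate receptor subunit gene gria2a and the vesicular glutamate transporter gene slc17a6b. Myelin and oligodendrocyte genes numbered 5 of 17 (29.4%), with 3 isoforms of mbpb, 2 of cnp, and 1 each of mpz and mag. Of the lists for other cells that a brain dissociate can hold, microglia and leukocytes had 3 of 22 (13.6%; mpx with 3, cd74a and cd74b with 1 each), and vessels, mural cells and fibroblasts had 3 of 22 (fli1a with 3, fn1b with 2 and tek with 1). The erythrocyte list was short, with 1 of 5 found genes (epb41b). Antioxidant, autophagy and mitochondrial genes had 5 of 26 (19.2%), among them lamp2 and atg7 with 2 isoforms each and sod2 and becn1 with 1. Adjusted p-values for these lists and for the EGF and FGF, senescence and inflammatory lists ran from 0.309 to 1 (Fisher's exact test, two-sided), and from 0.672 to 1 against matched lists (permutation test). Odds ratios to other genes, then to matched lists, were 1.35 and 0.69 for radial glia and 1.30 and 0.56 for neurons. They were 1.62 and 0.80 for oligodendrocytes, 0.61 and 0.43 for microglia, and 0.61 and 0.49 for vessels. For erythrocytes they were 0.97 and 0.45, and for antioxidant genes 0.93 and 0.61. Against lists matched on the number of exons, vessel genes passed the threshold in the direction of fewer class j isoforms (odds ratio 0.22, adjusted p = 0.036, permutation test). That matching leaves the number of annotated transcripts unequal. Members such as col1a1b (51 exons), flt4 and mrc1a (30 each) have 1 annotated transcript, though other members have more. No locus with 1 annotated transcript carried a class j isoform, so this deficit cannot be told apart from that imbalance. A class j isoform of a listed gene is a transcript model in the pooled catalogue and gives no level of expression.

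**Figure D2:**
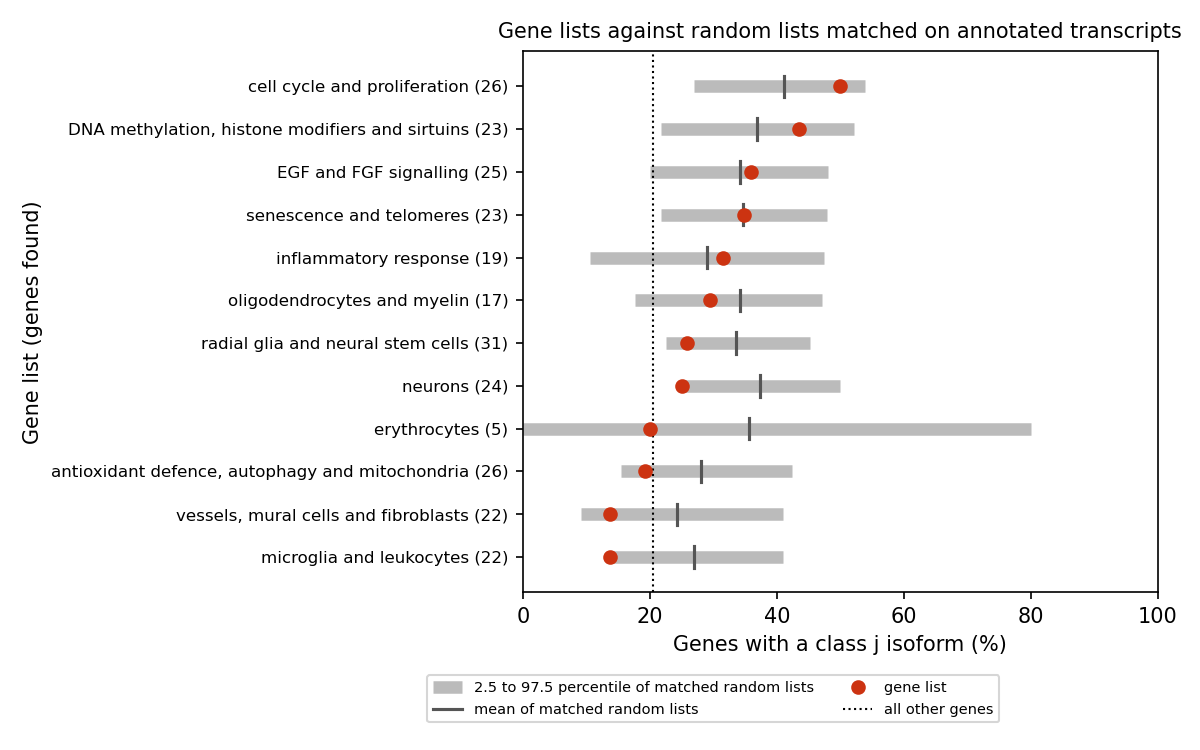
Percentage of the found genes of each list with at least 1 class j isoform (red points, x axis; lists on the y axis, with the number of genes found), beside the mean and the central 95% of 10000 random lists matched on annotated transcripts (line and grey bar) and the share of all other genes (dotted line, 20.4%). The cell cycle list, with 13 of its 26 genes, lies inside its matched range, and every other list also lies inside or at the edge of its own.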

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

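Of the alternatives, matching or restricting by annotated transcripts was chosen after the data had been seen. All 3 files shared 100% of their transcripts by exon structure, by intron chain and by 50% reciprocal overlap, and 61.5% of their whole lines, the rest differing in names. The counts of class j isoforms, and of loci and genes with one, stayed at 8347, 5910 and 5934 without transcripts under 200 nt, and were 8326, 5894 and 5918 without scaffolds. The counts for named genes stayed within 1.5 times the first under these choices and by nearest reference transcript. Those of the 10 gene names with the most class j isoforms did not change at all. Leaving out single-exon transcripts could not alter such counts, because a class j isoform has a junction. The number of lists past the threshold fell from 1 to 0 when transcripts replaced genes, against lists matched on annotated transcripts, and among genes with at least 2 annotated transcripts. The cell cycle odds ratio was then 1.52, 1.43 and 3.69, and 1.70 against lists matched on exons, all short of the threshold. Matched on exons, the list of vessels, mural cells and fibroblasts passed it (odds ratio 0.22, adjusted p = 0.036, permutation test). Exon matching does not equalise the number of annotated transcripts, so that deficit cannot be told apart from an imbalance in it. With the same matching, 2 others changed direction: neurons (0.73) and DNA methylation, histone modifiers and sirtuins (0.95). Matched on annotated transcripts, radial glia (0.69), neurons (0.56) and oligodendrocytes (0.80) changed direction, as did radial glia (0.95) and neurons (0.85) among genes with at least 2 annotated transcripts, and oligodendrocytes (0.93) by transcripts. None of these 8 reversals passed the threshold in either analysis, and the cause was not tested. No paired analysis was possible because the files hold no value per sample, and for the same reason the alternatives planned for expression values were not run.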

Other observations

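The catalogue places several genes at a single locus in 724 cases, 2.33% of all loci, involving 1697 gene names. The largest such locus holds 17 clustered protocadherin genes, from pcdh1g1 to pcdh1gc6, on chromosome 10 (21693447 to 21862679, plus strand), and 2 further protocadherin loci on chromosome 14 hold 15 and 13 names. Clustered protocadherins are cell adhesion molecules of neurons. On the plus strand of the mitochondrial genome, 1 locus runs from mt-co1 to mt-nd5 with 16 names and another holds mt-nd1 and mt-nd2 with 10. The 6 genes ugt1b1 to ugt1b5 and ugt1b7 of the glucuronosyltransferase family on chromosome 11 also form 1 locus. A value summed by locus would not separate the members of such clusters.

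Among the listed genes, 9 sit at loci of this kind. The telomere-binding protein gene terfa shares its locus with ikbip (chromosome 4, 76581353 to 76612256), and the interferon-induced gene mxa shares one with mxb (chromosome 1, 6878883 to 6920301). The antioxidant gene gpx1a shares its locus with brk1, and hbaa1, csf1rb, sox4a, mcm6, gria2a and mfap4 each share theirs with 1 other name. The 1 class j isoform at the sox4a locus and the 2 at the mfap4 locus carry the other name. Neither gene therefore counts as having one in the radial glia or microglia list. Assignment by nearest reference transcript left the odds ratios of these lists at 1.35 and 0.61. Across the catalogue, 413 class j isoforms contain introns annotated to more than 1 gene, such as the isoform of terfa with ikbip and that of mxa with mxb.

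The tests on introns, on the 3 files' names and on structures missing from a file were chosen after these values had been seen, while the bounds for single-transcript loci, other tissues and list matching were written before their values. Matching or restricting on annotated transcripts was itself chosen once the introns had been seen. A candidate explanation for the class j isoforms is that merging recombined parts of annotated transcripts. That 99.6% of the isoforms use annotated introns only was seen before this test was chosen, so it is no independent support. Assembly from reads across annotated introns could give the same share. That 0 loci with a single annotated transcript carry one largely follows from this share and adds no support either. Expression of the gene in these cultures would instead predict few class j isoforms in genes of tissues that brain cultures lack. Of 152 genes of lens, photoreceptors, muscle, liver, gut, pancreas, germ cells, kidney and thyroid, 44 had one (28.9%), including neb with 6, piwil1 and atp2a1 with 5, and vtg7 and gnat2 with 2. The share ran from 14.3% for pancreas and gut (3 of 21) and 19.4% for lens and photoreceptors (6 of 31) to 38.5% for kidney and thyroid (5 of 13), and single tissues were not matched separately. Random lists matched on annotated transcripts gave 31.6% on average (26.3% to 37.5%), an odds ratio of 0.88. The brain and proliferation lists had 32 of 98 (32.7%) against 36.5% in their matched lists, an odds ratio of 0.84, so genes of other tissues were no lower than these by this measure. The shortfall that expression would predict was therefore not seen over these tissues together. Expression in the cultures was not measured here for either set of genes, so the comparison cannot decide for or against expression as the determinant. No biological explanation by age could be tested.

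The same structures in all 3 files are not explained by 1 file deposited under 3 titles, because 7465 assembler names differ in at least 1 file. For separate assemblies of the age groups, 0% of the structures were missing from another file, a value seen before this test was chosen. Shared annotated introns could make separate assemblies alike, but would not by themselves do so for the 36 isoforms with an unannotated intron. These isoforms also had the same exons in all 3 files, as did those with an end off the annotated exon boundaries. The full match of 68373 structures argues against separate assembly from the reads of each age group. A repeated merge of 1 set of transcripts stays open and was not tested.

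The higher share of class j isoforms among cell cycle genes may come from their number of annotated transcripts, a median of 3 per gene. The odds ratio fell from 3.90 (1.81 to 8.42) to 1.43 when random lists were matched on that number, and 0 lists then passed the threshold. It was 3.69 among genes with at least 2 annotated transcripts (adjusted p = 0.168, Fisher's exact test), but that restriction does not equalise the number and weighs neither way. The 13 genes observed lie within the 7 to 14 of matched lists, and the explanation is left open. The planned bound was of little use, because only 1 list had passed before matching. A smaller excess cannot be told apart from none with 26 genes, since in simulations the matched test found a 6-fold rise in odds in only 36.0% of runs. Over all lists, 87 of the 263 genes found had 1 annotated transcript, and 0 of these carried a class j isoform. Multiplied odds add little for such members, so the simulated rise acted mainly on the rest of the list.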
